A study of Mus musculus with 28 samples.

How the data were processed

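The values used were made by the authors before they were deposited, 1 log2 signal per probe set and array. The labels do not state this unit, which was taken as log2 because values ran from 0.689 to 13.16, inside the range of the logarithm of a 16-bit scanner. Image reading, background handling, probe summary and any scaling between arrays are not given in the sources used here. Each array held 12488 probe sets, of which 66 controls were left out, and the other 12422 were quantile normalized because array medians spanned 0.218, more than the limit of 0.1 set beforehand. Gene symbols came from the array annotation, checked against gene identifiers of the reference, where 10839 were found and 0 symbols changed. A single symbol was given for 10855 probe sets, several for 396 and none for 1237. For each of 8251 genes the brightest probe set was kept, and the 5487 genes above the array median in at least 2 arrays were tested. Of these 1620 had more than 1 probe set, and the text says where another probe set had the opposite sign.

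Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 28 arrays, 18 residual degrees of freedom, a moderated t-test with a mean-variance trend and Benjamini-Hochberg adjustment within each comparison. A gene was called where adjusted p was under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Values after ± are standard deviations, and those marked SE come from the limma fit. Replicates were taken as unpaired.

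Gene lists were written from general knowledge of mouse liver and tested with camera at its preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry. Of 39 lists 37 had at least 5 tested genes and were tested. Beside each list the text gives the number of members called over all genes tested, and the number called when p was adjusted over the list alone.

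The comparisons, lists, scaling rule, brightness filter, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Mpg first. In each response to MMS it named the 5 largest rises and 5 largest falls among called genes whose values in the groups do not overlap. In comparisons of the genotypes and in interactions it named up to 10 called genes in each direction, for untreated liver without overlap. It added up to 4 members with the smallest adjusted p of each list described, and at every time Cdkn1a, Mdm2, Ccng1, Bax, Gdf15, Mgmt, Parp1, Polb, Xrcc1 and Apex1, whatever their values. Genes that mark the sex of the animal, markers used to describe arrays, and genes of the direct comparison of treated arrays were chosen after their values were seen.

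The alternatives fixed beforehand were the values as deposited with no scaling, median centring, no brightness filter, the mean of the probe sets of a gene, replicate number as a block, array weights, a fit with only the groups compared, and each array left out in turn. Starting offsets before taking logarithms were not run, since the values were already log2. Further alternatives were chosen after seeing the data. They were the array set of the hybridization controls as a term, each comparison within a set, the fit without the 3 arrays with female-typical transcripts, the array set and the female-typical pattern together as terms, and Aag against WT among treated arrays at each time. The array set as a term is estimated from the 4 Aag untreated arrays alone, the only group with arrays in both sets.

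The pipeline was tested on simulated arrays with the mean of each gene and its spread within groups. Of genes given a log2 change of 1, limma called 77.6% for WT at 6 h, 94% for WT at 12 h, 80.6% for Aag at 12 h and 92.5% for Aag at 24 h. For a change of 0.5 these were 23.9%, 37.3%, 26.9% and 40.3%, and with no effect added 0 genes were called over the 15 comparisons. The simulated values were independent normal draws, with a single data set for the case of no effect. They held no array sets, no female-typical arrays, no unequal array quality and no correlation between genes. These rates check the pipeline and do not give the error rates of the real arrays.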

Results

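The series asked how Aag, the glycosylase that removes alkylated bases such as 3-methyladenine from DNA, affects gene expression after methyl methanesulfonate (MMS), a DNA methylating agent. Total RNA from livers of wild-type (WT) and Aag null mice was measured on 28 Affymetrix MG-U74Av2 arrays. The WT arrays were 3 untreated, 2 at 6 h, 3 at 12 h, 2 at 24 h and 2 at 48 h after MMS. Among the Aag null arrays, called Aag here, 4 were untreated, 3 were taken at 6 h, 2 at 12 h, 4 at 24 h and 3 at 48 h. Values are log2 signals, which ran from 0.689 to 13.16. The number of arrays per group limits the precision. The labels do not say that replicates are separate animals, so each p-value measures spread between these samples. A gene is called higher or lower where its limma adjusted p was under 0.05 over the 5487 genes tested, and errors of differences are standard errors (SE).

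Mpg, the gene of the Aag glycosylase, gave a dim signal in all groups. Its mean was 2.73 ± 0.16 (SD, n = 3) in WT untreated liver and 2.35 ± 0.04 (SD, n = 4) in Aag untreated liver. Mpg was too dim to enter the main test, and without the brightness filter the untreated difference was -0.38 (SE 0.11, adjusted p = 0.0314). WT group means of Mpg lay from 2.59 to 2.73 and those of Aag groups from 2.35 to 2.47. Single arrays of the genotypes overlapped, with 2.38 in WT 6 h replicate 2 and 2.60 in Aag 24 h replicate 3. Whether the Mpg probes lie in the deleted part of the gene is not given in the sources used here.

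The 28 arrays fell into 2 sets by their hybridization controls, bacterial and phage transcripts added to each sample. The mean of the 9 control probe sets was 10.25 to 11.65 in 5 arrays and 6.42 to 9.22 in the other 23, with a gap of 1.03 between the sets. All 3 WT untreated arrays and Aag untreated replicates 3 and 4 formed the high set. Every treated array and Aag untreated replicates 1 and 2 formed the lower set. WT responses to MMS therefore have no value within a set, while each Aag response can be taken against the 2 untreated arrays of the lower set. The difference of the 3′ and 5′ Gapdh probe sets, a sign of RNA integrity and labelling, was 0.78 ± 0.15 (SD, n = 3) in WT untreated arrays, and its treated group means lay from -0.20 to 0.11. In Aag untreated liver it was 0.64 and 0.67 in replicates 3 and 4 of the high set. It was -0.19 and 0.02 in replicates 1 and 2 of the lower set, so it divided with the array set among untreated arrays.

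**Figure D1:**
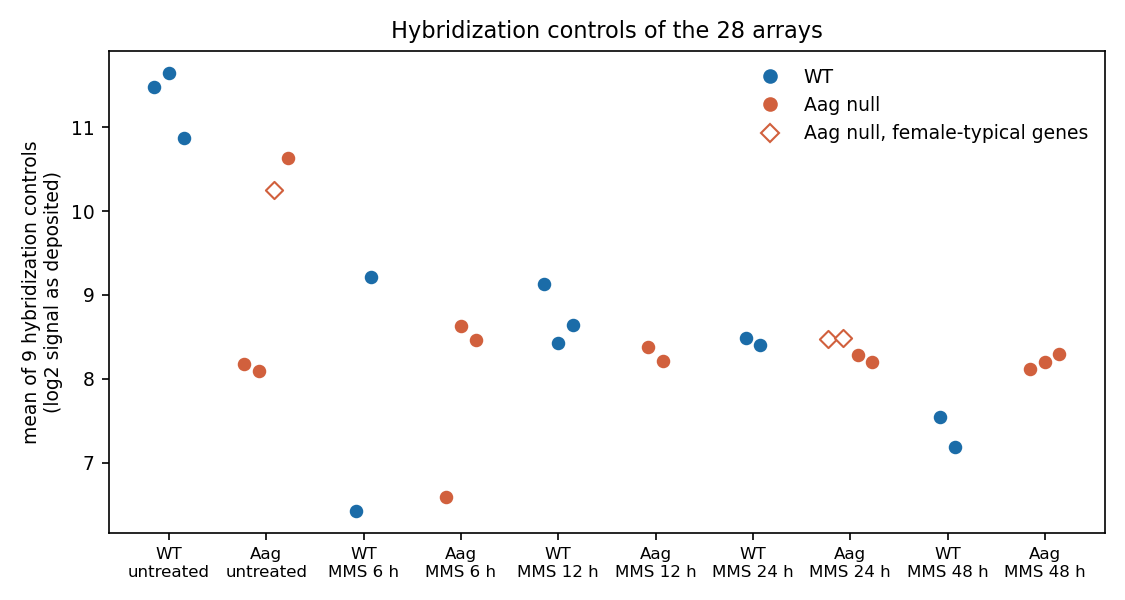
Mean log2 signal of the 9 hybridization control probe sets (vertical axis) in each of the 28 arrays by group (horizontal axis), with open diamonds for the 3 arrays that carry female-typical liver transcripts. The 5 arrays of the high set lie from 10.25 to 11.65 and the other 23 from 6.42 to 9.22.

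Transcripts that differ by sex in mouse liver set 3 arrays apart, Aag untreated replicate 3 and Aag 24 h replicates 1 and 2. Cyp2b9, a female-typical cytochrome P450, was 7.73 to 8.22 there and 2.49 to 4.21 in the other 25 arrays. Hsd3b5, a male-typical steroid dehydrogenase, was 2.94 to 5.27 against 6.73 to 8.65, and the Y-linked Eif2s3y was 2.47 to 2.59 against 3.29 to 5.53. Xist, expressed from the inactive X chromosome (2.03 to 2.69 against 1.43 to 2.06), and the Y-linked Uty (1.40 to 2.17 against 1.60 to 2.72) were dim and their ranges overlapped. The labels give no sex. Among arrays of a group, the 2 WT 6 h arrays were the least alike, with a correlation across genes of 0.837, and WT 6 h replicate 1 correlated with Aag 6 h replicate 1 at 0.984.

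In WT liver, the first comparison asked which genes changed by 6 h after MMS. Mt1, a metal-binding metallothionein, rose 29.2-fold (log2 4.87, SE 0.69, adjusted p = 0.000112, n = 2 against 3), and Mt2 rose 7.42-fold (SE 0.71 on a log2 change of 2.89). Of 22 tested genes of the unfolded protein response, 9 rose and 0 fell, and 12 rose when adjusted over the list alone. They included the chaperone partner Dnajb9 at 12.6-fold (log2 3.65, SE 0.60), Creld2 at 4.87-fold (SE 0.40), Herpud1 at 4.13-fold (SE 0.34) and the disulfide isomerase Pdia4 at 2.77-fold (SE 0.20). The acute phase response, liver-made plasma proteins of inflammation, had 12 of 24 genes higher and 1 lower, and 13 and 1 when adjusted over the list alone. Its members Serpina3n (4.26-fold, SE 0.27 on log2 2.09), Orm2 (4.03-fold, SE 0.34) and Itih4 (2.49-fold, SE 0.20) were among these, and serum amyloid Saa2 rose 12.4-fold (log2 3.63, SE 0.93, adjusted p = 0.0106). Both lists were called by camera with adjusted p = 5.45e-07, and both had adjusted p = 0.297 with an estimated correlation. The neutrophil chemokine Cxcl1 rose by 2.79 on the log2 scale (SE 0.78, adjusted p = 0.0177), a call that ended without WT 6 h replicate 1 (adjusted p = 0.231). Among the largest falls, Psen2, a subunit of gamma-secretase, fell by 2.22 (SE 0.28), and Reg2 of the regenerating family fell by 2.51 (SE 0.47). The potassium channel Kcnj9 fell by 3.15 (SE 0.50), Odf2 of sperm tails and centrosomes fell by 2.86 (SE 0.53) and the transporter Slc23a3 fell by 2.61 (SE 0.49), though other probe sets of each of these 3 genes had the opposite sign. In all, 893 genes were called, 387 higher and 506 lower. As deposited, with no scaling between arrays, 988 were called, 688 higher and 300 lower, and the median of all genes shifted by 0.113, 0.136, 0.151 and 0.123 at 6, 12, 24 and 48 h. With the array set as a term, 114 genes were called at 6 h (57 higher, 57 lower), 76 of them among the 893 with the same sign. Mt1 was then 6.96 and Mt2 4.72. Of the 19 called genes named by rule at this time, repair and p53 genes included, 8 kept their call and all 19 their sign. Dnajb9 was among those that lost it, at 2.36 (adjusted p = 0.163). Members higher were then 3 of the unfolded protein response (median 0.91) and 5 of the acute phase response (median 0.55, from 0.72), with 0 lower in each, and camera called both (adjusted p = 4.63e-05 and 3.89e-05). Without WT 6 h replicate 2 the count was 1543, and with array weights limma called 0 of 5487 (323 at unadjusted p under 0.05). A fit of these groups alone called 21.

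At 12 h, Mt1 was still 17.3-fold higher (log2 4.11, SE 0.61, adjusted p = 9.18e-05, n = 3 against 3) and Mt2 7.48-fold higher (SE 0.64). The acute phase response had 12 of 24 genes higher and 0 lower, and 12 higher and 1 lower when adjusted over the list alone. Orm2 was 4.93-fold higher (log2 2.30, SE 0.31), Serpina3n 3.55-fold (SE 0.24), Itih4 2.25-fold (SE 0.18) and Saa2 12.4-fold (SE 0.83). Camera called this list with median 0.62 and adjusted p = 8.23e-05, the adjusted p was 0.712 with an estimated correlation, and with the array set as a term 5 genes were higher and 0 lower, with a median of 0.33 (adjusted p = 0.00144). The unfolded protein response had 2 genes higher and 0 lower of 22, 1 when adjusted over the list alone, and was not called (camera adjusted p = 0.289). Mrm3, a methyltransferase of mitochondrial ribosomal RNA, was 4.56-fold higher (SE 0.40). The largest falls were those of Kcnj9 (-3.53, SE 0.45), Odf2 (-3.11, SE 0.47), Slc23a3 (-2.81, SE 0.44), Igfbp1, a binding protein of insulin-like growth factors (-2.74, SE 0.74, adjusted p = 0.0115), and Reg2 (-2.63, SE 0.42). Other probe sets of Kcnj9, Slc23a3 and Reg2 had the opposite sign, and Igfbp1 had adjusted p = 0.056 without WT 12 h replicate 1. The count was 1155 genes, 598 higher and 557 lower, against 1301 as deposited (954 higher, 347 lower). It fell to 727, 681 and 721 without WT 12 h replicates 1, 2 and 3. With the array set as a term 166 genes were called (96 higher, 70 lower), 111 of them shared with the 1155. Of the 17 called genes named by rule at this time, repair and p53 genes included, 5 kept their call and all 17 their sign. Mrm3 (0.18, adjusted p = 0.867) and Igfbp1 (-0.10, adjusted p = 0.976) were among those that lost it.

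At 24 h, Mt1 was 11.7-fold higher (log2 3.55, SE 0.69, adjusted p = 0.00144, n = 2 against 3). The phosphatidate phosphatase Lpin1 was 6.22-fold higher (SE 0.68, adjusted p = 0.013) and Saa2 10.6-fold (SE 0.93, adjusted p = 0.017), and both lost their call without WT 24 h replicate 1 (adjusted p = 0.125 and 0.132). Nr1d2, a repressor of the circadian clock, was 4.92-fold higher (log2 2.30, SE 0.39, adjusted p = 0.000586). Its WT untreated arrays (2.70 to 3.01) lay below the Aag untreated arrays (4.12 to 4.68) and all treated arrays (4.21 to 6.14). A response of Nr1d2 to MMS and an offset of the WT untreated arrays therefore cannot be told apart. Erdr1 was 13.6-fold higher (SE 0.65), with another probe set of the opposite sign. Kcnj9, Odf2, Slc23a3 and Reg2 again gave large falls, from -3.66 to -2.73, with opposite signs in other probe sets of all but Odf2, and A4galt, a glycolipid galactosyltransferase, fell by 2.76 (SE 0.47). The acute phase response had 6 of 24 genes higher and 3 lower, the same when adjusted over the list alone, and no list was called by camera at this time. The count was 759 genes, 364 higher and 395 lower, against 938 as deposited (702 higher, 236 lower) and 315 with these groups alone in the fit. It was 240 and 220 without WT 24 h replicates 1 and 2. It was 192 with the array set as a term (124 higher, 68 lower), 114 of them shared with the 759. Of the 14 called genes named by rule at this time, repair and p53 genes included, 4 then kept their call. All 14 kept their sign, and the changes of 8 moved by more than 1.5 times.

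At 48 h, targets of the nuclear receptor PPARalpha and genes of fatty acid oxidation stood out, with 7 of 25 higher and 1 lower, and 9 and 1 when adjusted over the list alone. Cpt1a, which controls fatty acid entry into mitochondria, was 2.43-fold higher (log2 1.28, SE 0.24, adjusted p = 0.00114, n = 2 against 3). Hadhb of the mitochondrial beta-oxidation complex was 2.05-fold higher (SE 0.15), the peroxisomal Pex11a 2.06-fold (SE 0.16, adjusted p = 0.0507 with the array set as a term) and the carnitine carrier Slc25a20 1.70-fold (SE 0.17). The list had camera adjusted p = 0.00622, adjusted p = 0.0562 as deposited and adjusted p = 0.963 with an estimated correlation, and its median went from 0.50 to 1.05 with the array set as a term. Nr1d2 was 5.95-fold higher (SE 0.39), Erdr1 10.9-fold (SE 0.65), Mrm3 5.45-fold (SE 0.45), Rnf13, a membrane ubiquitin ligase, 5.12-fold (SE 0.41) and Dnajb9 4.56-fold (SE 0.60). The change of Nr1d2 again rests on the low WT untreated arrays. Dnajb9 had adjusted p = 0.17 without WT 48 h replicate 2. Kcnj9, Odf2, Reg2 and Slc23a3 were lower by -3.43 to -2.85, again with opposite signs in other probe sets of all but Odf2, and Igfbp1 by -2.66 (SE 0.83), which lost its call without WT 48 h replicate 1 (adjusted p = 0.259). The count was 792 genes, 347 higher and 445 lower, against 819 as deposited (548 higher, 271 lower), 388 with array weights (146 higher, 242 lower) and 307 with these groups alone in the fit. It was 482 and 305 without WT 48 h replicates 1 and 2. It was 194 with the array set as a term (105 higher, 89 lower), 116 of them shared. Of the 19 called genes named by rule at this time, repair and p53 genes included, 5 then kept their call and all 19 their sign. Among those that lost it, Igfbp1 was -0.03 (adjusted p = 0.991), Mrm3 0.43 (adjusted p = 0.494) and Dnajb9 0.90 (adjusted p = 0.57).

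**Figure D2:**
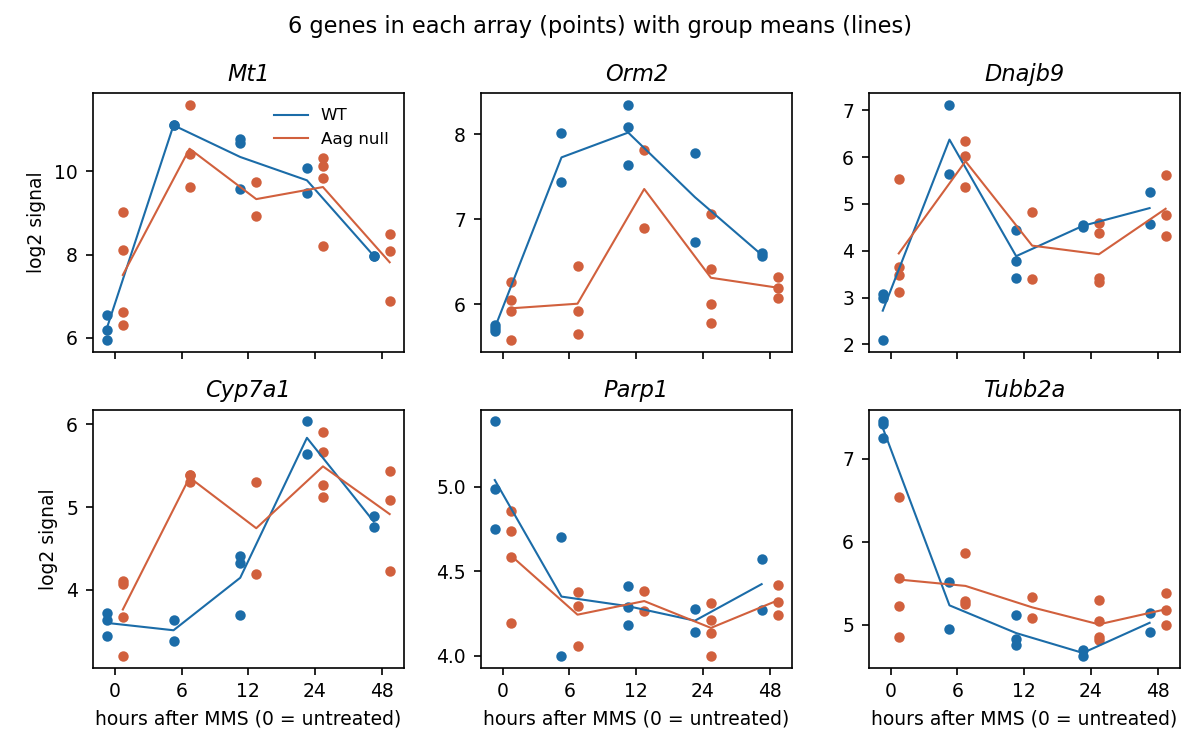
Log2 signal (vertical axis) of Mt1, Orm2, Dnajb9, Cyp7a1, Parp1 and Tubb2a in each array, with lines through group means, against condition (horizontal axis, evenly spaced from untreated to 48 h) for WT and Aag liver. In WT liver Mt1 has a mean of 6.23 untreated, lies at 11.1 in both arrays at 6 h and has a mean of 10.34 at 12 h. Cyp7a1 is higher at 24 h than in untreated liver in both genotypes, at 5.84 against 3.60 in WT and 5.49 against 3.76 in Aag liver. The courses differ before that. At 6 h WT arrays lie at 3.383 and 3.638 and Aag arrays from 5.3 to 5.39, and at 12 h Aag arrays lie at 5.304 and 4.186.

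In Aag liver, the same question at 6 h gave Mt1 8.15-fold higher (log2 3.03, SE 0.57, adjusted p = 0.0171, n = 3 against 4). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.02-fold higher, from 3.76 ± 0.43 (SD, n = 4) to 5.36 ± 0.05 (SD, n = 3), with SE 0.28 and adjusted p = 0.0139. The membrane protein Cd99 (2.19-fold, SE 0.25), the signalling adaptor Shc1 (1.91-fold, SE 0.18) and Nrbp2 (1.73-fold, SE 0.17) were also higher. Kcnj9 fell by 2.01 (SE 0.42), Pigk of GPI anchor attachment by 1.39 (SE 0.30), Otulinl by 1.13 (SE 0.23), Rpa2, a subunit of the single-strand DNA binding complex RPA, by 1.10 (SE 0.21), and the phospholipase Pla2g4f by 1.03 (SE 0.20). Camera called 3 lists in which 0 genes passed over all genes tested. These were the unfolded protein response (median 0.28, adjusted p = 0.00902, and 0.577 with an estimated correlation), targets of NRF2, which controls antioxidant genes (median 0.27, adjusted p = 0.0118, and 0.298), and PPARalpha targets (median -0.27, adjusted p = 0.017, and 0.662). When adjusted over the list alone 1, 1 and 0 of their 22, 20 and 25 genes passed, and within the lower set the PPARalpha median was 0.02 (adjusted p = 0.383) and that of the unfolded protein response 0.18 (adjusted p = 0.0387). Without the female-typical arrays the PPARalpha list had adjusted p = 0.131 and the NRF2 median was 0.18, and with the replicate block the PPARalpha list had adjusted p = 0.0559. The count was 28 genes, 15 higher and 13 lower, with 761 at unadjusted p under 0.05, against 100 as deposited (82 higher, 18 lower), 98 with array weights (36 higher, 62 lower), 2 with the replicate block and 0 by limma with these groups alone in the fit (417 at unadjusted p under 0.05). Against the 2 untreated arrays of the lower set 11 genes were called, with Mt1 at 4.07 (adjusted p = 0.00112) and Cyp7a1 at 1.92 (adjusted p = 0.00506), and 5 of the 28 were among them. The other 8 of the 10 genes named here lost their call there. Each of the 7 arrays moved the count by more than 1.5 times when left out, to 133, 82, 5 and 5 without Aag untreated replicates 1, 2, 3 and 4, and to 0, 11 and 10 without Aag 6 h replicates 1, 2 and 3. Each of the 10 genes lost its call without at least 1 array, Cyp7a1 without Aag 6 h replicate 1 (adjusted p = 0.058).

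At 12 h in Aag liver, targets of the glucocorticoid receptor had 2 of 16 genes higher and 0 lower, and 6 and 0 when adjusted over the list alone. Fkbp5, a co-chaperone of that receptor, was 2.54-fold higher (log2 1.34, SE 0.21, adjusted p = 0.00446, n = 2 against 4) and the tyrosine aminotransferase Tat 2.77-fold higher (SE 0.27, adjusted p = 0.0236). The list had camera adjusted p = 0.00087, and 0.0811 with an estimated correlation, and its median went from 0.32 to 0.59 within the lower set. Slc25a25, a mitochondrial carrier, was 2.90-fold higher (SE 0.30), Fmo5 2.57-fold (SE 0.30) and Sidt2 1.67-fold (SE 0.16). Lower genes were Kcnj9 (-2.20, SE 0.48), Pigk (-1.59, SE 0.34), Rpa2 (-1.19, SE 0.23), the steroid dehydrogenase Hsd17b2 (-1.16, SE 0.22), Pla2g4f (-1.13, SE 0.23), fibrinogen Fgg (-0.92, SE 0.21) and the lipid droplet protein Plin2 (-0.83, SE 0.18). PPARalpha targets had 0 of 25 higher and 1 lower (0 and 2 when adjusted over the list alone, median -0.35, camera adjusted p = 0.000164, and 0.679 with an estimated correlation), and their median was -0.01 within the lower set (adjusted p = 0.655). The acute phase response had 0 of 24 higher and 1 lower, but 6 and 2 when adjusted over the list alone (median 0.34, camera adjusted p = 0.0165, and 0.679 with an estimated correlation). Its camera adjusted p was 0.327 as deposited, 0.147 with the replicate block and 0.0602 within the lower set. Camera also called cholesterol synthesis (median -0.21, adjusted p = 0.0165, and 0.679 with an estimated correlation), the proteasome (-0.23, 0.0041 and 0.769) and endothelial markers (-0.20, 0.0499 and 0.27), with 0 genes past the test in each, and 2 lower genes of cholesterol synthesis when adjusted over the list alone. Within the lower set the proteasome (-0.07, adjusted p = 0.292) and endothelial markers (0.0722) lost their call, the latter also as deposited (0.0653), and cholesterol synthesis had a median of -0.13 with the replicate block. The count was 24 genes, 9 higher and 15 lower, with 611 at unadjusted p under 0.05, against 15 as deposited (9 higher, 6 lower). It was 555 with array weights (277 higher, 278 lower), 7 with the replicate block and 3 with these groups alone in the fit. Within the lower set 19 were called (13 higher, 6 lower), 7 of them shared with the 24, among them Fkbp5 at 1.61 and Slc25a25 at 1.72. Of the 12 genes named here 7 kept their call as deposited and 2 within the lower set, and each lost it without at least 1 array. The count was 89, 46, 4 and 8 without Aag untreated replicates 1, 2, 3 and 4, and 0 without either array at 12 h.

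At 24 h in Aag liver, Cyp7a1 was 3.32-fold higher (log2 1.73, SE 0.26, adjusted p = 0.00203, n = 4 against 4). In WT liver Cyp7a1, looked up after its values were seen, was higher by 2.24 at 24 h (SE 0.33, adjusted p = 0.000159) and 1.23 at 48 h (adjusted p = 0.0152), and the responses differed by -0.51 at 24 h (adjusted p = 0.728). Noct, a clock-controlled phosphatase, was higher by 1.93 on the log2 scale (SE 0.36), the deubiquitinase Usp2 2.40-fold (SE 0.25), Tat 2.12-fold (SE 0.22) and the glutathione transferase Mgst3 2.11-fold (SE 0.26). The circadian clock list had 1 of 11 genes higher, Usp2, and 3 when adjusted over the list alone (median 0.42, and 0.24 within the lower set, camera adjusted p = 0.018, and 0.308 with an estimated correlation). Kcnj9 fell by 1.71 (SE 0.39), Pigk by 1.19 (SE 0.27), the endoplasmic reticulum chaperone Hspa5 by 1.14 (SE 0.27), Mob1b by 1.10 (SE 0.26) and Rpa2 by 1.02 (SE 0.19). Proteasome genes had 1 of 30 lower, Psmd1 (-0.46, SE 0.10), and 2 when adjusted over the list alone (median -0.34, camera adjusted p = 1.47e-07, and 0.713 with an estimated correlation). Markers of Kupffer cells, the macrophages of liver, had 0 of 13 genes past the test (median -0.41, adjusted p = 0.000147, and 0.502). Fatty acid synthesis had 0 of 12, and 3 higher when adjusted over the list alone (median 0.36, adjusted p = 0.0114, and 0.713), with adjusted p = 0.183 as deposited. Male-biased liver genes had 0 of 10, and 1 lower when adjusted over the list alone (median -0.36, adjusted p = 0.00719, and 0.713), and without the 3 female-typical arrays, 2 of which belong to this group, their adjusted p was 0.116 and that of fatty acid synthesis 0.152. Within the lower set the median of male-biased genes was -0.75 and that of the proteasome -0.21. Without the female-typical arrays these were -0.09 and -0.21, and with the array set and the female-typical pattern as terms -0.24 and -0.11 (adjusted p = 0.00173 and 0.0497). The count was 59 genes, 26 higher and 33 lower, with 823 at unadjusted p under 0.05, against 108 as deposited (84 higher, 24 lower), 370 with array weights (204 higher, 166 lower) and 5 with these groups alone in the fit. Within the lower set 54 were called (38 higher, 16 lower), 18 of them shared with the 59. Of the 11 genes named by rule 4 kept their call there, among them Noct, Usp2 and Mgst3. Without the 3 female-typical arrays 1 gene was called, Cyp7a1 at 2.13 (adjusted p = 0.0132). The count was 198, 22 and 30 without Aag untreated replicates 1, 3 and 4, and 16, 9, 22 and 28 without Aag 24 h replicates 1, 2, 3 and 4. Cyp7a1 and Usp2 alone of the 11 genes named by rule kept their call with every array left out in turn.

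At 48 h in Aag liver, cholesterol synthesis had 1 of 16 genes lower, Hmgcs1 (-1.59, SE 0.39, adjusted p = 0.0474, n = 3 against 4), and 5 when adjusted over the list alone. The list had camera adjusted p = 0.000391, and 0.672 with an estimated correlation. Interferon response genes had 2 of 14 lower, the ubiquitin-like Isg15 (-0.61, SE 0.13) and the immunoproteasome subunit Psmb9 (-0.56, SE 0.11), and 4 when adjusted over the list alone (median -0.14, and -0.25 within the lower set, camera adjusted p = 0.0133, and 0.691 with an estimated correlation). Proteasome genes had 1 of 30 lower, Psmd4 (-0.47, SE 0.10), the same when adjusted over the list alone (median -0.23, and -0.12 within the lower set, adjusted p = 0.000403, and 0.826), and with the array set and the female-typical pattern as terms its adjusted p was 0.0521. The amino acid transporter Slc7a2 was 2.25-fold higher (SE 0.25), Cyp7a1 2.23-fold (SE 0.28), Tat 2.06-fold (SE 0.24), Rab6a 1.82-fold (SE 0.19) and the glutathione transferase Gsta2 1.71-fold (SE 0.17). The transcription factor Atf5 fell by 1.11 (SE 0.20), H2-Ke6 by 1.00 (SE 0.19), the cysteine dioxygenase Cdo1 by 0.95 (SE 0.19) and Ang by 0.90 (SE 0.21). The count was 50 genes, 17 higher and 33 lower, with 930 at unadjusted p under 0.05, against 70 as deposited (48 higher, 22 lower) and 25 with median centring (4 higher, 21 lower). Array weights gave 962 (518 higher, 444 lower), the replicate block 13 and a fit of these groups alone 0 by limma (963 at unadjusted p under 0.05). Within the lower set 14 were called, 5 of them shared with the 50, among them Cyp7a1 at 1.48 and Gsta2 at 0.94 and 0 of the other 11 genes named here, and without the 3 female-typical arrays limma called 0 (527 at unadjusted p under 0.05). The count was 476, 0 and 10 without Aag untreated replicates 1, 3 and 4, and 23, 0 and 0 without Aag 48 h replicates 1, 2 and 3, and each of the 13 genes lost its call without at least 1 array.

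**Figure D3:**
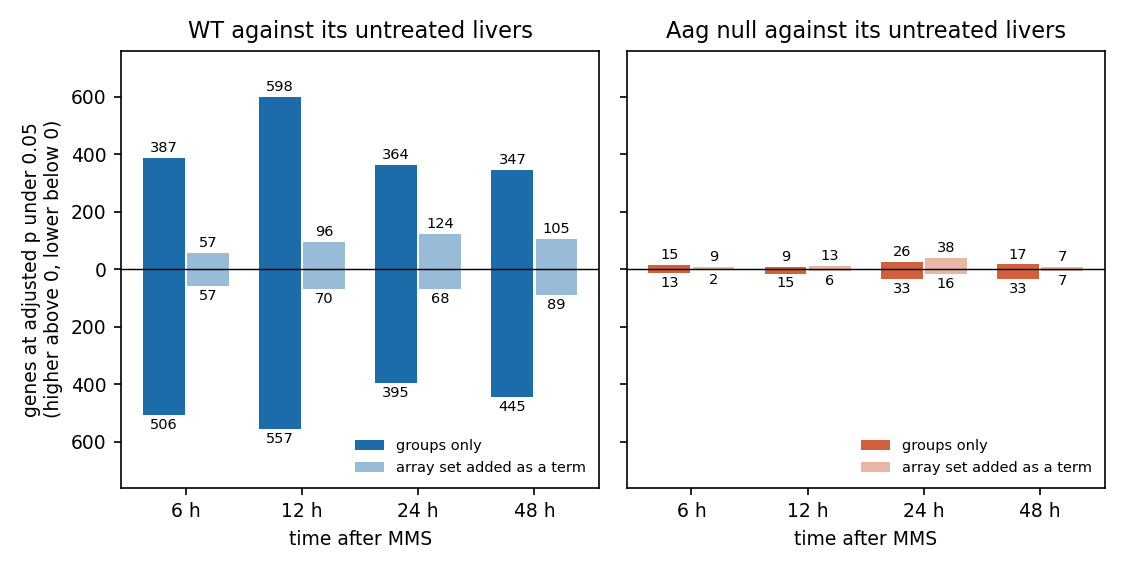
Number of genes called higher and lower than untreated liver (vertical axis) at 6, 12, 24 and 48 h after MMS (horizontal axis) in WT and Aag liver, from groups alone and with the array set as a term. WT counts fell from 893, 1155, 759 and 792 to 114, 166, 192 and 194 with the term, and Aag counts went from 28, 24, 59 and 50 to 11, 19, 54 and 14.

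Genes called in both genotypes moved the same way at all 4 times. At 6 h, 8 were higher and 10 lower in both, where 1.06 and 1.2 would fall together by chance. At 12 h the numbers were 6 and 11 (0.981 and 1.52 by chance), at 24 h 17 and 24 (1.72 and 2.38) and at 48 h 12 and 20 (1.08 and 2.68), with 0 genes in opposite directions. Across genes, which are not independent replicates, the log2 changes of the genotypes had Pearson r 0.69, 0.68, 0.621 and 0.514 and Spearman rho 0.637, 0.639, 0.539 and 0.453 at 6, 12, 24 and 48 h. The chance values take the responses as independent, which they were not, and r carries the same link, because all WT and 2 of 4 Aag untreated arrays lie in the high set and all treated arrays in the lower. Of the genes called in WT at 12 h, 78.3% had the same sign in Aag untreated arrays of the lower set minus those of the high set. The shared genes numbered 18, 17, 41 and 32 in all, 71, 12, 85 and 38 as deposited, and 2, 2, 1 and 0 without the female-typical arrays. The array set as a term gave 7, 14, 42 and 12, where both responses rest on the same 2 Aag untreated arrays.

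Repair genes and p53 targets were followed at every time. Parp1, which senses DNA strand breaks, was lower in WT liver by -0.69 (SE 0.20, adjusted p = 0.0217), -0.75 (SE 0.18, adjusted p = 0.00511), -0.83 (SE 0.20, adjusted p = 0.00788) and -0.62 (SE 0.20, adjusted p = 0.042) at 6, 12, 24 and 48 h. In Aag liver Parp1 differed by -0.35, -0.27, -0.43 and -0.27, with adjusted p = 0.353, 0.645, 0.191 and 0.431. The interaction for Parp1 did not pass the test at any time (adjusted p = 0.758, 0.669, 0.616 and 0.6). Before treatment Parp1 was 4.59 in Aag against 5.04 in WT liver (-0.45, adjusted p = 0.129). Treated group means lay from 4.208 to 4.424 in WT and from 4.165 to 4.327 in Aag liver. The single-strand break repair scaffold Xrcc1 was lower in WT liver at 12, 24 and 48 h, by -0.69 (SE 0.22), -0.90 (SE 0.25) and -0.82 (SE 0.25), and at 6 h it was -0.64 (adjusted p = 0.0809). In Aag liver Xrcc1 differed by -0.39, -0.24, -0.15 and -0.09 at the 4 times, none past the test. Its interaction was not called either (adjusted p = 0.894, 0.831, 0.399 and 0.344), and it differed by -0.54 before treatment (adjusted p = 0.137). With the array set as a term Parp1 in WT liver was -0.83, -0.88, -0.97 and -0.75 (adjusted p = 0.177, 0.107, 0.0791 and 0.172), larger falls that were no longer called. Xrcc1 was then -0.64, -0.84 and -0.76 at 12, 24 and 48 h (adjusted p = 0.425, 0.239 and 0.272), also not called. As deposited, Parp1 had adjusted p = 0.0581 at 6 h and 0.0979 at 48 h, and Xrcc1 0.0671 at 12 h and 0.0549 at 48 h. At worst, Parp1 lost its call without WT 6 h replicate 1 (adjusted p = 0.275), WT 24 h replicate 2 (0.1) or WT 48 h replicate 2 (0.312). At worst, Xrcc1 lost its call without WT untreated replicate 2 (0.108) at 12 h, WT 24 h replicate 1 (0.136) and WT 48 h replicate 2 (0.435). Apex1, the main abasic site nuclease, differed by 0.26, -0.31, -0.23 and -0.13 in WT and -0.12, -0.10, -0.39 and -0.14 in Aag liver, none past the test. Mgmt, which repairs O6-methylguanine directly, and Polb, the polymerase of base excision repair, were too dim to enter the main test. Without the brightness filter Mgmt differed by -0.05, 0.06, 0.20 and 0.12 in WT and -0.13, -0.005, 0.01 and -0.01 in Aag liver, and Polb by -0.01, -0.20, -0.006 and -0.11 in WT and 0.01, 0.06, -0.17 and -0.27 in Aag liver, none past the test. The base excision repair list had 1 higher and 2 lower of 10 genes in WT at 6 h and 0 and 3 at each later time, 1 and 3 at 6 h and 0 and 3 later when adjusted over the list alone, and camera did not call it (adjusted p = 0.697, 0.289, 0.158 and 0.508).

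Cdkn1a, the p53-induced inhibitor of the cell cycle, differed in WT liver by -0.23, -0.25, -0.33 and -0.33 at 6, 12, 24 and 48 h (adjusted p = 0.431, 0.32, 0.27 and 0.264), and Mdm2, the p53 ubiquitin ligase, by 0.32, 0.13, 0.25 and 0.15 (adjusted p = 0.295, 0.671, 0.451 and 0.686). In Aag liver Cdkn1a differed by -0.06, -0.07, 0.07 and 0.05, and Mdm2 by 0.40, 0.14, 0.11 and 0.07, none past the test. Of the 16 tested p53 targets 2, 2, 1 and 1 were higher and 0, 1, 1 and 2 lower in WT liver at these times, and 1, 3, 4 and 1 higher and 0, 1, 2 and 2 lower when adjusted over the list alone. The epoxide hydrolase Ephx1 was higher at 6, 12 and 48 h (0.76, 0.75 and 1.10), the kinase Plk3 at 6 and 12 h (0.72 and 0.76), Sesn1 at 24 h (0.90), and Zmat3 was lower at 12, 24 and 48 h (-0.49, -0.50 and -0.53). In Aag liver 0 of the 16 passed in limma at any time, and 0 when adjusted over the list alone. Camera did not call the list in WT liver (adjusted p = 0.502, 0.668, 0.634 and 0.887). The array set as a term ended each call of Ephx1, Plk3, Sesn1 and Zmat3, and all but those of Ephx1 at 12 and 48 h ended without at least 1 array. Ccng1 was too dim to enter the main test, and without the filter it differed by 0.43, 0.23, 0.28 and 0.24 in WT and 0.31, -0.005, 0.10 and 0.10 in Aag liver, none past the test. Bax and Gdf15 have no probe set on the array.

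Before treatment, Aag liver was compared with WT liver. Besides genotype, the groups differed in array set, and 1 Aag array was female-typical. Clock genes, looked up after their values were seen, differed too, with Nr1d1 at 4.55 to 4.68 in WT and 5.19 to 5.96 in Aag arrays. Nr1d2, Cry1 and Tef did not overlap either, while Dbp, Usp2, Arntl and Nfil3 did. The hour of collection is not given, so the differences cannot be credited to the loss of the glycosylase by itself. G6pc, which releases glucose from liver, was 3.79-fold lower in Aag (log2 -1.92, SE 0.36, adjusted p = 0.00378), at 7.96 ± 0.13 (SD, n = 4) against 9.88 ± 0.45 (SD, n = 3). The tubulins Tubb2a (-1.83, SE 0.25) and Tubb6 (-1.03, SE 0.17), Rpa2 (-1.10, SE 0.21), Ssr4 of the endoplasmic reticulum (-1.08, SE 0.25), Tmem150a (-1.04, SE 0.18), the clock repressor Cry1 (-1.03, SE 0.17), Tspan3 (-1.03, SE 0.18), the Wnt carrier Wls (-1.01, SE 0.23) and the retinal reductase Dhrs3 (-0.996, SE 0.144) were also lower. Higher genes included Erdr1 (2.50, SE 0.54), Nr1d2 (1.54, SE 0.33), Pip4k2c (1.48, SE 0.33), the matrix proteoglycan Dcn (1.22, SE 0.28), Igbp1 (1.19, SE 0.24), Wdr26 (1.09, SE 0.28), Atxn10 (1.06, SE 0.27), the Y-linked Sry (1.05, SE 0.15) and Mkrn1 (1.01, SE 0.25). Other probe sets of Erdr1, Pip4k2c, Wdr26, Atxn10, Sry, Mkrn1 and Tubb2a had the opposite sign. As the groups do not overlap, Sry in the female-typical replicate 3 of Aag lay above all 3 WT untreated arrays. PPARalpha targets had 3 of 25 genes higher and 0 lower, Cpt1a (2.18-fold, SE 0.20), Hadhb (1.58-fold, SE 0.13) and Slc25a20 (1.41-fold, SE 0.14), and 5 when adjusted over the list alone (camera adjusted p = 0.0125, and 0.99 with an estimated correlation). Kupffer cell markers had 0 of 13 past the test and 2 higher when adjusted over the list alone (median 0.26, camera adjusted p = 0.0412, and 0.99). Without the female-typical array, replicate 3 of Aag, both lists lost their call (adjusted p = 0.376 and 0.411), and PPARalpha targets did with the replicate block (0.061). Within the high set the median of PPARalpha targets went from 0.31 to 0.61, with 9 of 25 genes higher (adjusted p = 2.17e-11), and with the female-typical pattern as a further term it was 0.66, where Kupffer cell markers had adjusted p = 0.0893. The count was 247 genes, 110 higher and 137 lower, against 210 as deposited (116 higher, 94 lower) and 23 with array weights (5 higher, 18 lower). Within the high set, with 2 Aag arrays and 3 WT arrays, 170 were called (91 higher, 79 lower), 93 of them shared with the 247, with Tubb2a at -2.33 and G6pc at -1.81, and 14 of the 23 genes named by rule kept their call. Replicate 3, 1 of those 2 Aag arrays, is female-typical, and with the female-typical pattern as a further term 87 were called (52 higher, 35 lower), 48 of them shared with the 247. Of the 23, 9 lost it without at least 1 array, among them Erdr1 without WT untreated replicate 1 (adjusted p = 0.0533) and Slc25a20 without WT untreated replicate 2 (0.127). The count was 151 without WT untreated replicate 1, 141 without Aag untreated replicate 1 and 157 without Aag untreated replicate 2, and 2 when the 7 untreated arrays alone entered the fit.

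Averaged over the 5 conditions, Aag liver had lower acute phase genes and higher Kupffer cell markers than WT liver. Of 24 acute phase genes 0 were higher and 2 lower, and 0 and 11 when adjusted over the list alone, with a median of -0.27. The members past the test were Saa2 (3.96-fold lower, log2 -1.98, SE 0.40, adjusted p = 0.0344) and Itih4 (1.48-fold lower, SE 0.09, adjusted p = 0.00737), and Orm2 was 1.62-fold lower (SE 0.15, adjusted p = 0.0516). Of 13 Kupffer cell markers 1 was higher, the complement subunit C1qa (1.41-fold, SE 0.10, adjusted p = 0.0292), and 12 were higher when adjusted over the list alone, with a median of 0.30. Both lists had camera adjusted p = 1.3e-18 and adjusted p = 0.00637 with an estimated correlation, the only calls of the 44 made by camera over all comparisons that held with it. Among the treated arrays alone, all of the lower set, the acute phase median was -0.36 and the Kupffer median 0.32, with adjusted p = 0.00311 and 0.00763 with an estimated correlation. Before treatment camera called the Kupffer list but not the acute phase list. The acute phase interaction over the mean of the 4 times had a median of -0.395. The lower acute phase average is therefore not shown for untreated liver. Over the 5 conditions Gamt of creatine synthesis (1.28-fold, SE 0.06) and the peroxisomal Pxmp2 (1.21-fold, SE 0.05) were also higher. The serum amyloid pseudogene Saa-ps (1.67-fold, SE 0.14), the securin Pttg1 (1.49-fold, SE 0.09) and the protease inhibitor Serpina10 (1.25-fold, SE 0.06) were lower. These 8 genes, 3 higher and 5 lower, were all that passed, with 267 at unadjusted p under 0.05. Camera called 6 further lists with 0 genes past the test in each, which were interferon response (median 0.10, adjusted p = 0.000177, and 0.212 with an estimated correlation), the unfolded protein response (-0.05, 0.000633 and 0.29), cholesterol synthesis (0.09, 0.000694 and 0.336), hepatocyte functions (0.06, 0.00186 and 0.212), male-biased genes (-0.24, 0.00668 and 0.429) and the proteasome (-0.02, 0.0252 and 0.677). Without the 3 female-typical arrays the adjusted p of male-biased genes was 0.966 and that of the proteasome 0.0912. With the array set as a term the proteasome had adjusted p = 0.24, and with the female-typical pattern as a further term cholesterol synthesis (0.134) and hepatocyte functions (0.158) lost their call too. Saa2, Itih4, C1qa, Gamt, Pxmp2 and Serpina10 lost their call as deposited (adjusted p = 0.0526, 0.127, 0.0514, 0.243, 0.355 and 0.547). The count was 2 genes as deposited, 1 with median centring, 5 with the replicate block and 0 by limma with array weights (124 at unadjusted p under 0.05). It was 13 among treated arrays (5 higher, 8 lower) and 3 without the female-typical arrays. It was 24 without WT 6 h replicate 1, 5 without Aag untreated replicate 3, WT 48 h replicate 1 or Aag 12 h replicate 1, and 4 without WT 12 h replicate 1, Aag 6 h replicate 3, Aag 12 h replicate 2 or Aag 48 h replicates 1 or 3. C1qa and Saa-ps lost their call at worst without WT 24 h replicate 1 (adjusted p = 0.107 and 0.128), and Saa2 and Serpina10 without Aag 12 h replicate 2 (0.126 and 0.0878).

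**Figure D4:**
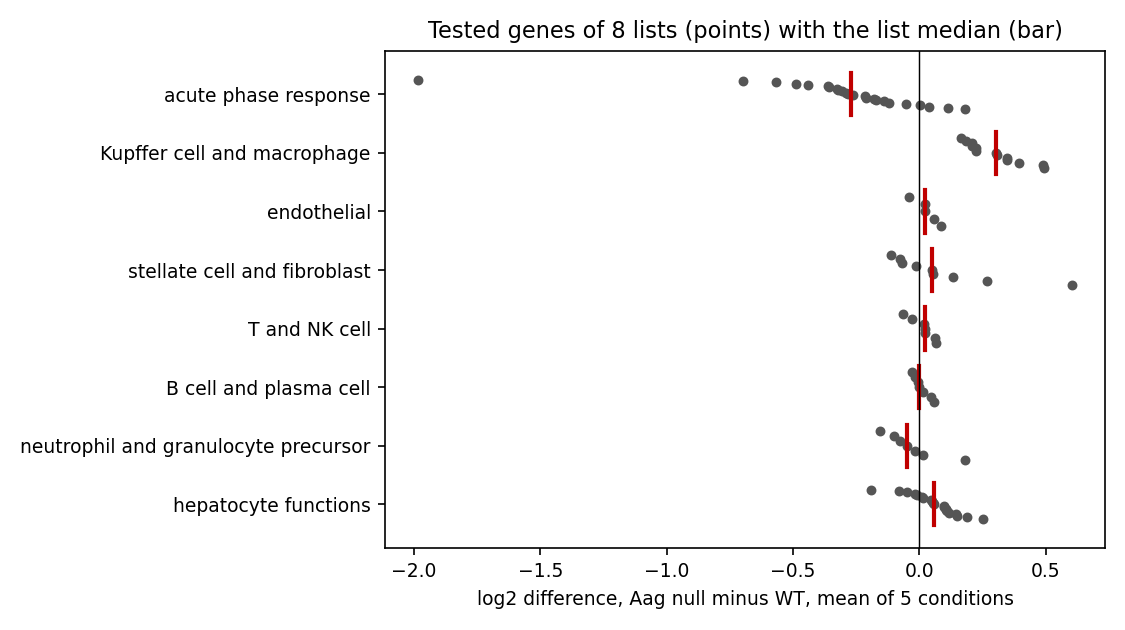
Log2 difference of Aag minus WT over the 5 conditions (horizontal axis) for each tested gene of 8 lists (vertical axis), with a bar at each median. All 13 Kupffer cell markers lie above 0 with a median of 0.30, and 4 of the 24 acute phase genes do, with a median of -0.27.

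A direct comparison of Aag with WT at each time after MMS was added after the data had been seen, because all treated arrays lie in the lower set. At 6 h Aag liver had higher Cyp7a1 (1.85, SE 0.33, adjusted p = 0.0124), the uridine phosphorylase Upp2 (1.62, SE 0.34), Gamt (1.03, SE 0.14), Tcea3 (0.76, SE 0.13) and Pxmp2 (0.56, SE 0.11). Lower there were Orm2 (-1.72, SE 0.34, adjusted p = 0.0336), Saa-ps (-1.61, SE 0.34), Itih4 (-1.44, SE 0.20), Serpina10 (-1.09, SE 0.14) and Pdia4 (-0.99, SE 0.20). At 12 h 1 gene passed, Serpina10 (-0.88, SE 0.14, adjusted p = 0.0132), and at 24 and 48 h limma called 0, with 68 and 194 at unadjusted p under 0.05. The 6 h count of 10 genes was 806 without WT 6 h replicate 1, 18 without WT 6 h replicate 2 and 4 without Aag 6 h replicate 3. It was 4 as deposited, 2 with median centring (Cyp7a1 and Tcea3), 5 with the replicate block, and 0 by limma with array weights and with only these arrays in the fit (12 and 54 at unadjusted p under 0.05). The call of Serpina10 at 12 h ended as deposited, with median centring, and without WT 12 h replicate 1 or replicate 2. Array weights gave 53 genes there and a fit of these arrays alone 19. These genes were named after their values were seen.

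The difference between the responses of the genotypes was tested as an interaction. Tubb2a differed at all 4 times, by 2.06 (SE 0.40), 2.14 (SE 0.40), 2.17 (SE 0.38) and 1.99 (SE 0.40) at 6, 12, 24 and 48 h, though its other probe set had the opposite sign at 6, 12 and 24 h. Its level differed before treatment, at 7.37 in WT and 5.55 in Aag liver, and treated arrays of both genotypes lay from 4.62 to 5.86. The acute phase gene Itih4 (-1.64, SE 0.27) and the protease inhibitor Serpina10 (-1.36, SE 0.18) had lower responses in Aag liver at 6 h, where those of the methyltransferase Bhmt (1.72, SE 0.32) and of Hgd of tyrosine breakdown (1.24, SE 0.21) were higher. At 12 h G6pc differed by 2.84 (SE 0.56) and at 24 h the water channel Aqp8 by 1.49 (SE 0.24). Over the mean of the 4 times Cpt1a (-1.26, SE 0.24), Nr1d2 (-1.60, SE 0.38) and Hadhb (-0.66, SE 0.15) were lower and G6pc (2.03, SE 0.42) higher. The acute phase response had 1 gene lower and 0 higher of 24 at 6 h, and 3 lower when adjusted over the list alone (median -0.64, camera adjusted p = 7.8e-09, and 0.258 with an estimated correlation). PPARalpha targets over the mean of the 4 times had 4 of 25 lower and 0 higher, and 7 and 1 when adjusted over the list alone (median -0.40, adjusted p = 0.000303, and 0.907). Their median was -0.71 with the array set as a term, with 8 lower, and -0.26 without the female-typical arrays, with 1 lower (adjusted p = 0.0176). Counts were 13 genes at 6 h (10 higher, 3 lower), 9 at 12 h (6 and 3), 2 at 24 h (2 and 0), 11 at 48 h (9 and 2) and 97 over the mean of the 4 times (62 and 35). All interactions rest on the untreated arrays, which divide between the 2 sets, and with the set as a term the counts were 34, 28, 24, 73 and 131, with 12, 8, 2, 9 and 58 of the calls kept. Without the female-typical arrays they were 11, 0, 0, 0 and 45, with array weights 0, 16, 13, 4 and 2, and leaving out 1 array gave 9 to 102, 0 to 24, 0 to 31, 0 to 59 and 42 to 399. The highest of these came without WT 6 h replicate 1 at 6 h, WT untreated replicate 3 at 12, 24 and 48 h, and WT 6 h replicate 2 over the mean, and 4, 9, 10, 9 and 21 arrays moved the count by more than 1.5 times.

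**Figure D5:**
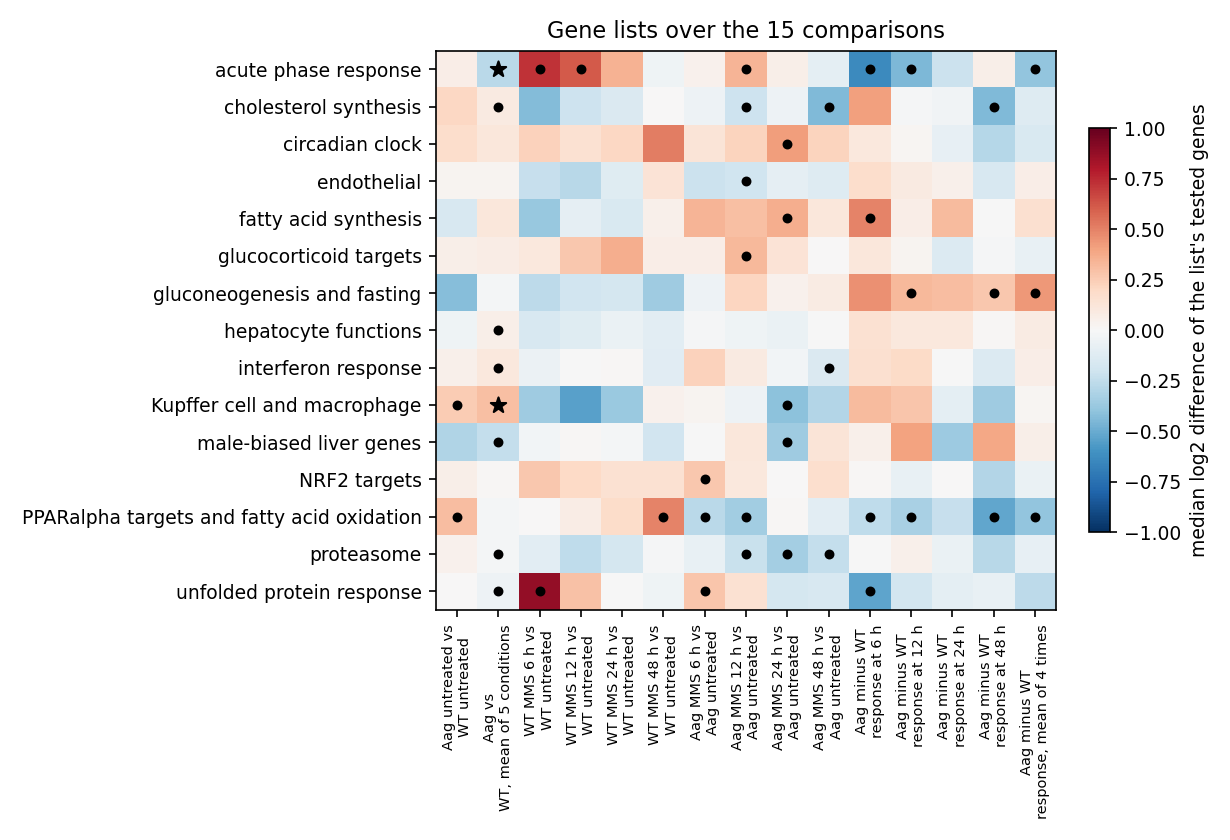
Median log2 difference (colour) of 15 gene lists (vertical axis) in the 15 comparisons (horizontal axis), with a dot where camera called the list and a star where the call held with an estimated correlation. The stars are those of the acute phase response at -0.27 and Kupffer cell markers at 0.30 in Aag against WT over the 5 conditions.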

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

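The tests for the array set as a term in WT liver and for the 3 female-typical arrays, the comparison among treated arrays, and the last test of a smaller Aag change, with the error of each group, were chosen after the result was seen, and the test before it was set after an earlier one, as said below.

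WT livers gave many more called genes after MMS than Aag livers, 1155 against 24 at 12 h, but with array weights the numbers were 1379 against 555, and Aag gave more at 6 h (98 against 0 by limma, the latter with 323 at unadjusted p under 0.05) and at 48 h (962 against 388). A smaller change of Aag livers from a shared starting level stays open, because 2 tests of it were void, the median signed Aag change within the lower set (0.131) over the WT change with the array set as a term (0.375) since its genes were chosen for being called in WT, and the effect spread of treated Aag minus WT at 12 h over that of the WT response, set after the first was seen, since its value of 0 is a floor (mean squared difference 0.0292 under the pooled squared error of 0.0514, and a ratio of 0.457 with no subtraction), and in another, with the error of each group, that spread of 0.122 lay -0.0568 from the 0.179 that a shared start needs (0.413 in WT less 0.234 in Aag), within 2 jackknife SE of 0.0797, though it lay below at every time (-0.0737, -0.109 and -0.165 at 6, 24 and 48 h, SE 0.182, 0.11 and 0.0952, at the floor at 6 and 48 h). In the main fit the start was not alike, with 247 genes called between untreated genotypes and 170 within the high set. Treated genotypes differed by 10, 1, 0 and 0 genes at 6, 12, 24 and 48 h. Array weights gave 23 untreated and 0, 53, 3 and 0 treated. A fit of the compared groups alone gave 2 untreated and 0, 19, 0 and 0 treated, so the counts do not decide. The array set of the hybridization controls stays open, because over the WT genes the Aag untreated arrays of the lower set differed from those of the high set by 0.394 of the WT change (0.243 of 0.616), with 78.3% of the genes in the same direction. With the set as a term 9.61% of the calls (111 of 1155) were kept, while the median change went from 0.616 to 0.375, its SE from 0.159 to 0.232, and 92.4% of genes had the same sign, so both a smaller change and a larger error ended calls. A response to MMS and a batch effect cannot be told apart for the calls that ended. Those kept, such as Mt1 (4.11, and 6.20 with the term), are separated from the set only if it acts alike in both genotypes. That could not be checked, since no WT group has arrays in both sets. For Mt1, Aag untreated arrays were 9.015 and 8.098 in the high set and 6.62 and 6.308 in the lower set. WT untreated arrays, all of the high set, were 5.953 to 6.557. The larger change of Mt1 with the term thus came from the 2 Aag arrays of the high set.

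The 3 Aag arrays with female-typical liver transcripts had Eif2s3y, a Y-linked gene, below every other array in 3 of 3. Eif2s3y was itself among the genes whose score picked these arrays, so this alone is not independent support. The female-typical Cyp2b9 sets the same 3 arrays apart by itself (7.73 to 8.22 against 2.49 to 4.21). With the arrays picked that way, the low Eif2s3y goes with female animals among the Aag mice. The dim Xist (2.03 to 2.69 against 1.43 to 2.06) and Y-linked Uty (1.40 to 2.17 against 1.60 to 2.72) overlapped the other arrays and do not decide. Nor does the Y-linked Sry, higher without overlap in Aag than WT untreated liver, female-typical array included, but with another probe set of opposite sign. A loss of the male growth hormone pattern in male mice would leave Eif2s3y inside the range of the other arrays. With the arrays picked by Cyp2b9, 0 of the 3 were inside it, which argues against such a loss on this gene alone. A swap with a WT array would need a WT array with this pattern, and 0 had it. Labels that name another sample outside the series were not tested.

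Acute phase genes were lower and Kupffer cell markers higher in Aag liver over the 5 conditions. The division into a high and a lower set is excluded as the cause, since treated arrays, all of the lower set, kept the pattern. Their acute phase median was -0.357 (camera adjusted p = 3.25e-27, 0.00311 with an estimated correlation) and that of Kupffer cell markers 0.32 (5.47e-19, and 0.00763). Hybridization controls still ran from 6.42 to 9.22 among these arrays. The controls were lower in WT than in Aag liver at 48 h, higher at 12 h, and overlapped at 6 and 24 h. A processing difference within the lower set was not tested and stays open. Without the female-typical arrays the medians kept their sign, at -0.282 (camera adjusted p = 3.5e-20) and 0.232 (5.96e-16). This argues against these arrays as the cause without excluding it, since camera was run there at its preset correlation only. A lower share of hepatocytes would raise markers of other cells alike, but the endothelial median lay -0.278 from that of Kupffer cells (0.0241 with 4 of 5 genes above 0, against 0.302 with 13 of 13 and quartiles of 0.21 and 0.349), and hepatocyte genes were at 0.0563. A genotype difference in inflammatory tone or in Kupffer cell number stays open as a hypothesis from the same data, and neither was tested. For the acute phase list a difference before treatment is not shown, since camera did not call it in untreated liver.

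Other splits of the same arrays were counted for comparisons of at least 3 arrays per group. For untreated Aag against WT the real split called the most genes (247, highest other 233, 1 of 35 splits). That highest other split, which put Aag replicates 3 and 4 with WT replicates 1 and 3, took 4 of the 5 arrays of the high set. Within that set, where 1 of the 2 Aag arrays is the female-typical replicate 3, 170 genes were called, and 87 with the female-typical pattern as a further term. The real split also called the most for Aag at 24 h (59, highest other 19, 1 of 35). Without the female-typical arrays 1 gene was called there. Both shares lie under 0.05, but 1 of 35 is the lowest share that 35 splits can give. The comparisons were not adjusted for one another, so these 2 results argue against chance without excluding it. WT at 12 h has 10 splits, too few for a share under 0.05 (1155, highest other 0, 1 split as large). Chance cannot be excluded for Aag at 6 h (28, highest other 1097, 4 of 35), where Aag 6 h replicate 1 joined the 2 untreated arrays of the high set, which points to a structure of the samples, and within the lower set 11 genes were called. Nor can it for Aag at 48 h (50, highest other 619, 2 of 35), where Aag untreated replicates 2, 3 and 4 stood against the rest, also a structure of the samples, and within the lower set 14 genes were called. It cannot be excluded for Aag against WT over the 5 conditions (8, highest other 2293, 5 of 100 draws), where 4 draws called more than 3 times the real count, which points to a structure of the samples, though no array carried the other genotype in all 4, so which arrays make it was not settled. The same holds of chance for the mean interaction (97, highest other 244, 8 of 100 draws).

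The interaction between MMS and genotype passed the test for 13 genes at 6 h, 9 at 12 h, 2 at 24 h, 11 at 48 h and 97 over the mean of the 4 times. It does not tell a different response from a different untreated level, and Tubb2a was 7.37 in WT and 5.55 in Aag untreated liver and 4.62 to 5.86 in the 21 treated arrays of both genotypes. At 6 h the interaction was positive for Tubb2a (2.06), Tmem150a (1.77), Bhmt (1.72), Dhrs3 (1.36), Tubb6 (1.29), Hgd (1.24), Slc46a1 (1.01), Tcea3 (0.93), Plxnb2 (0.78) and Ttr (0.72), and negative for Slc5a6 (-0.86), Serpina10 (-1.36) and Itih4 (-1.64). At 12 h it was positive for G6pc (2.84), Tubb2a (2.14), Bhmt (1.76), Tmem150a (1.43), Cry1 (1.29) and Hgd (1.09), and negative for Slc5a6 (-1.02), Serpina10 (-1.14) and Itih4 (-1.29). At 24 h it was positive for Tubb2a (2.17) and Aqp8 (1.49). At 48 h it was positive for Tubb2a (1.99), Rpa2 (1.52), Tspan3 (1.41), Cry1 (1.30), Ip6k1 (1.12), Ube2c (0.95), Mettl18 (0.95), Apobec2 (0.95) and Pomgnt1 (0.73), and negative for Eef1d (-1.01) and Polr1d (-1.50). Over the mean of the 4 times it was positive for Tubb2a (2.09), G6pc (2.03), Cyp2c70 (1.45), Tmem150a (1.27), Bhmt (1.26), Hba-a1 (1.23), Ssr4 (1.195), Tubb6 (1.11), Rpa2 (1.10) and Tspan3 (1.09). It was negative there for Pex11a (-0.61), Slc25a20 (-0.63), Hadhb (-0.66), Gclm (-0.76), Slc5a6 (-0.79), Polr1d (-0.93), Sry (-0.93), Ppp2r5c (-0.94), Nr1d1 (-0.95), Itih4 (-0.96), Igbp1 (-1.19), Cpt1a (-1.26) and Nr1d2 (-1.60). Of these 13, 9, 2, 11 and 23 named genes 12, 8, 2, 9 and 17 kept their call with the array set as a term, and 8, 0, 0, 0 and 14 without the female-typical arrays. Each of the 9, 2 and 11 genes at 12, 24 and 48 h lost its call without at least 1 array.

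The same test by camera called 13 lists, none of them with an estimated correlation. At 6 h the medians were -0.64 for the acute phase response (adjusted p = 7.8e-09, 0.258 with an estimated correlation), -0.531 for the unfolded protein response (1.17e-05, 0.427), 0.496 for fatty acid synthesis (0.00273, 0.79) and -0.253 for PPARalpha targets (0.00918, 0.79). At 12 h they were -0.453 for the acute phase response (0.000629, 0.93), -0.325 for PPARalpha targets (9.86e-05, 0.93) and 0.323 for gluconeogenesis and fasting (0.0161, 0.93). At 48 h they were -0.523 for PPARalpha targets (7.31e-06, 0.658), -0.443 for cholesterol synthesis (0.0433, 0.658) and 0.269 for gluconeogenesis and fasting (0.0489, 0.658). Over the mean of the 4 times they were -0.395 for the acute phase response (0.0065, 0.907), 0.437 for gluconeogenesis and fasting (0.0267, 0.907) and -0.395 for PPARalpha targets (0.000303, 0.907). With the array set as a term the calls of gluconeogenesis and fasting ended at 12 h, 48 h and over the mean (adjusted p = 0.586, 0.558 and 0.611, the last with a median of 0.121), as did that of the acute phase response over the mean (0.0637), while PPARalpha medians went to -0.516, -0.743, -0.9 and -0.708 at 6, 12 and 48 h and over the mean. Without the female-typical arrays the PPARalpha median at 6 h was 0.0576 (adjusted p = 0.156), that over the mean -0.255 (adjusted p = 0.0176) and the call of cholesterol synthesis ended (0.0562), and as deposited that of gluconeogenesis and fasting at 48 h did (0.0623). With both terms the calls of gluconeogenesis and fasting (0.512, 0.61 and 0.644), the acute phase response over the mean (0.0898) and cholesterol synthesis (0.251) ended. Members past the test over all genes were 1 lower of 24 acute phase genes at 6 h, at 12 h and over the mean, 1 higher of 10 gluconeogenesis genes at 12 h and over the mean, and 4 lower of 25 PPARalpha targets over the mean.

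A sample far from the others was found for 3 measures in the 2 groups of 4 arrays, by the gap to the nearest array over the range of the group. Zmat3 was low in Aag untreated replicate 1 (0.935), Noct high in Aag 24 h replicate 1 (0.89) and Rpa2 low in Aag 24 h replicate 2 (0.882), each above Dixon's 95% critical value for 4 arrays. These were 1 of 59 measures in Aag untreated liver and 2 of 13 in Aag liver at 24 h, and chance gives about 1 in 20.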

How the results depend on the processing

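The alternatives with the array set, within a set, without the female-typical arrays and with both terms, and the comparison of Aag with WT among treated arrays, were chosen after the result was seen. Counts below are genes called, and the cause was not tested except where said.

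With values as deposited, Aag against WT over the 5 conditions went from 8 to 2, Aag responses from 28 to 100 at 6 h, 24 to 15 at 12 h and 59 to 108 at 24 h, and interactions from 9 to 3 at 12 h, 11 to 2 at 48 h and 97 to 45 over the mean. Treated Aag against WT gave 4 at 6 h and 0 at 12 h, and genes shared by the genotypes numbered 71 at 6 h and 85 at 24 h. With median centring the 5 conditions gave 1, Aag at 48 h 25, interactions 6, 0, 1 and 2 at 6, 12, 24 and 48 h, and treated Aag against WT 2 at 6 h and 0 at 12 h. With no filter, where more genes were tested, untreated Aag against WT gave 535, Aag at 12 h 15, and interactions 24, 19, 23 and 54 at the 4 times and 278 over the mean. With the mean of probe sets the interaction gave 5 and treated Aag against WT 2, both at 12 h.

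The replicate numbers were not taken as pairs, since of 32 pairs of equal number 12 correlated above 0.1 and 13 below -0.1, and in 0 of 5 comparisons with at least 3 pairs did every pair lie above 0.1. Between the genotypes all 6 pairs at 6, 24 and 48 h did, from 0.118 at 48 h to 0.919 at 6 h, while both at 12 h lay below -0.1, and the block moved the direct comparison at 6 h from 10 to 5. With the number as a block the 5 conditions gave 5, Aag responses 2 at 6 h, 7 at 12 h and 13 at 48 h, interactions 2 at 48 h and 54 over the mean, while the other comparisons stayed within 1.5 times. With only the groups compared in the fit, which leaves fewer arrays to estimate the error, untreated Aag against WT gave 2, WT responses 21 at 6 h, 315 at 24 h and 307 at 48 h, Aag responses 0, 3, 5 and 0 at the 4 times, interactions 0 at 6 h, 1 at 24 h and 0 at 48 h, and treated Aag against WT 0 at 6 h and 19 at 12 h. With array weights untreated Aag against WT gave 23, the 5 conditions 0, WT responses 0 at 6 h and 388 at 48 h, Aag responses 98, 555, 370 and 962, interactions 0, 16, 13 and 4 and 2 over the mean, and treated Aag against WT 0 at 6 h, 53 at 12 h and 3 at 24 h. The weights were 0.128 for both WT 6 h arrays and 4.63 for WT 12 h replicate 3.

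With the array set as a term the 5 conditions gave 14, WT responses 114, 166, 192 and 194, Aag responses 11 at 6 h and 14 at 48 h, and interactions 34, 28, 24 and 73. Genes shared by the genotypes were then 7 at 6 h and 12 at 48 h, a count that the term itself raises, since responses of both genotypes then rest on the same 2 Aag untreated arrays, and 94 list tests were called in place of 44. Within a set the 5 conditions gave 13 and Aag responses 11 at 6 h and 14 at 48 h, with fewer arrays. Without the female-typical arrays the 5 conditions gave 3, Aag responses 4, 3, 1 and 0, interactions 0, 0 and 0 at 12, 24 and 48 h and 45 over the mean, treated Aag against WT 2 at 12 h, and shared genes 2, 2, 1 and 0. With both terms untreated Aag against WT gave 87, WT responses 107, 157, 160 and 162, Aag responses 11 at 6 h, 33 at 24 h and 13 at 48 h, interactions 32, 21, 20 and 42, and list tests 73. With both terms Igfbp1 in WT liver reversed, from -2.74 to 0.29 at 12 h (adjusted p = 0.934) and from -2.66 to 0.36 at 48 h (adjusted p = 0.872).

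Leaving out 1 array at a time gave 141 to 349 for untreated Aag against WT, 4 to 24 for the 5 conditions, 666 to 1543, 681 to 1117, 220 to 851 and 305 to 820 for WT responses, and 0 to 133, 0 to 89, 9 to 198 and 0 to 476 for Aag responses. For interactions it gave 9 to 102, 0 to 24, 0 to 31 and 0 to 59, and 42 to 399 over the mean. Treated Aag against WT gave 4 without Aag 6 h replicate 3 to 806 without WT 6 h replicate 1, 0 to 2 at 12 h, 0 to 1 at 24 h and 0 to 1 at 48 h. The highest counts of the Aag responses came without Aag untreated replicate 1, that of WT at 6 h without WT 6 h replicate 2, and that of the mean interaction without WT 6 h replicate 2. In groups of 2 arrays the array left alone was assumed to vary like the other groups.

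Of 44 list tests called by camera, 2 were called with an estimated correlation, and fry called 37, of which 9 were among the 44. As deposited 39 of the 44 were kept, with the replicate block 41, with the array set as a term 34, without the female-typical arrays 35 and with both terms 29, and none was called in the opposite direction. In 4 of the 44 the median changed sign without a call. For PPARalpha targets in Aag liver at 6 h it went from -0.27 to 0.02 with the array set as a term and with both terms (adjusted p = 0.383 and 0.372), and in the interaction at 6 h from -0.253 to 0.0576 without the female-typical arrays (adjusted p = 0.156). Over the 5 conditions male-biased genes went to 0.028 without those arrays (adjusted p = 0.966), and the proteasome to 0.00229 with the array set as a term and 0.0293 with both terms (adjusted p = 0.24 and 0.675).

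Of 204 values of named genes past the test, 51 lost their call as deposited, 59 with median centring, 12 with no filter, 59 with the block, 112 of 173 with only the groups compared, 18 of 187 with the mean of probe sets, 99 with array weights, 102 with the array set as a term, 45 of 77 within a set, 90 without the female-typical arrays and 121 with both terms, besides the 2 reversed Igfbp1 values, which were no longer called. At least 1 array left out ended the call of 116 of the 204. Apart from those 2, none of the 204 changed sign under these alternatives. Of 250 values not past the test, 11, 5, 4, 0, 2, 3, 26, 8, 2, 1 and 8 passed under these alternatives in the same order. Offsets before the logarithm were not run, as the values were already log2. Signal over background limits dim genes such as Mpg, whose group means of 2.35 to 2.73 lie under the array medians of 3.97 to 4.18.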

Other observations

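The genes here were chosen after the result was seen, and no test was run on them beyond those of the report. Dbp, an output gene of the circadian clock, was 3.69 to 4.02 in the 3 WT untreated arrays, and in Aag untreated liver it was 3.62 to 3.88 in the 2 arrays of the lower set and 6.30 to 6.79 in the 2 of the high set. Among the 21 treated arrays Dbp was 4.48 to 5.93. Nr1d2 was 2.70 to 3.01 in WT untreated, 4.12 to 4.68 in Aag untreated and 4.21 to 6.14 in treated arrays. Cry1, its counterpart in the negative arm of the clock, was 5.34 to 6.16, 4.45 to 4.81 and 4.13 to 5.15 in the same order. Tef was 6.79 to 7.22, 7.42 to 8.12 and 7.5 to 8.51, and Arntl, which was too dim to be tested, was 2.80 to 3.83, 2.39 to 3.11 and 2.43 to 2.79. For Nr1d2, Cry1 and Tef the WT untreated arrays lay outside the range of all other arrays, while Dbp and Arntl overlapped. WT responses of those genes therefore do not tell MMS from an offset of the WT untreated arrays. The labels do not give the hour of the day at which livers were taken.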
